A study of Zea mays with 57 samples.

How the data were processed

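Shoots of 10-day-old maize seedlings (inbred line B73) were profiled by 3' end RNA sequencing with unique molecular identifiers. The 57 libraries fall into 19 groups of 3: the start of the experiment at 0 min, and nitrogen or KCl medium at each of 9 times from 5 to 120 min. Each replicate is a pool of tissue from 3 seedlings, per the labels' protocols, so the spread between replicates is a spread between pools.

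The values analysed are whole-number counts per gene, deposited by the authors without normalization. Per the submitters' processing notes the tools were UMI-tools 1.1.1, fastp 0.21.0, STAR 2.7.6a and featureCounts 2.0.1, whereas the header of the deposited count table names featureCounts 1.5.1. Per the file headers, counting used release 37 of the AGPv4 annotation and no strand option was set, so reads from a gene and an antisense or overlapping neighbour cannot be told apart. The authors also deposited a quantile-normalized table, whose values are treated here as a score because they were rounded to whole numbers and share the same total, 2522105, in each of its 55 libraries; it holds 18370 genes and neither replicate 3 library of the 120 min groups. How that table was made beyond the quantile step is not given in the sources used here. The authors' network table gives 1 score, called a weight, for each pair of a regulator and a target, and its making is likewise not given in the sources used here. The count table held 2 columns that match no labelled sample, and these were not used.

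Gene names were available for few genes. The reference table of gene names follows another assembly (Zm-B73-REFERENCE-NAM-5.0), and 0 of the 44146 nuclear gene IDs of the count table occur in it. Names were therefore given only to organelle genes. The plastid models numbered 74, of which 27 had the same start and end in that table, and 97 of the 144 mitochondrial models did. A model took a name when exactly 1 protein-coding gene overlapped it and shared its start or end, which named 20 of the models tested, of which 7 were plastid and 21 mitochondrial. Other models are called by the genes they span. Coordinates are those of the count table.

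Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr on the 19 groups, and the quasi-likelihood F test on a model of 19 group means over all 57 libraries, with 38 residual degrees of freedom. Of 46335 genes, 18412 were tested. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05. Each SE of a log2 change was derived from its test, as the absolute log2 change divided by the square root of F. It is not a separate estimate of error, and for large effects or low counts the SEs of related contrasts need not match. The contrasts were the mean nitrogen minus KCl difference over 9 times, the 9 differences jointly, the means over 5 to 30 min (early) and over 45 to 120 min (late), late minus early, each time alone, and KCl medium minus the start at 30 min, at 120 min and at any time. These designs, the rule for named genes, 39 gene lists and the first set of alternatives below were set before the data were examined. On simulated counts with known changes, the average contrast recovered 99% of genes changed 1.5-fold and 100% of those changed 3-fold, and called 14 of the unchanged among 18186 genes. The contrast at 5 min recovered 24% and 98%, and that at 120 min 15% and 95%. Late minus early recovered 58% and 100% on 18034 genes, and KCl 120 min minus start 20% and 96% on 18032 genes. The simulation drew each gene independently around the trend of spread with abundance, without a spread shared between genes. It changed only genes above a minimum abundance. Recovery and false calls in the real libraries may therefore differ.

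The 39 fixed lists rest on gene names and descriptions. Only 1 of them, cytosolic ribosomal proteins, had tested members, and its 3 members are organelle genes that match its symbol pattern. No list reached the minimum of 5 tested members, so no fixed list was tested. In their place 6 groups that need no names were added after the data were seen: the network table's regulators, its other targets, plastid genes, mitochondrial genes, microRNA genes and other nuclear non-coding RNA genes. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. None of the 154 microRNA IDs passed the filter.

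The rule for named genes takes genes with an informative name, which leaves out names that start with orf or ycf, a mean of at least 5 counts per 1000000 (CPM), an adjusted p under 0.05 and, for the average, the same sign at 8 or more of the 9 times; it takes the largest changes in each direction. It also asked for members of the fixed lists and for leading network regulators, none of which carries a name here. Its parts for the early and late means would name organelle genes alone, whose values are given with the average, and its part for KCl medium, which also asked that all 3 libraries of one group lie above all 3 of the other, found no gene with an informative name at 30 or 120 min. Because the files do not pair nuclear IDs with names, at most 2 IDs that rose and 2 that fell are printed for a comparison, chosen by the same rule without the name. All other organelle models are described as members of their group, and those the text singles out, orf names included, lie outside the rule and were chosen after their values were seen. CPM values are TMM-scaled. CPM means and SDs leave out 1 library with 8560 counts (nitrogen 120 min, replicate 3), which stays in the model, so nitrogen means have n = 26.

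The first set of alternatives was RLE size factors, library totals alone, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the 6 libraries compared, a natural cubic spline of time with 3 degrees of freedom, and leaving out each library in turn. Further alternatives were chosen after the data were seen: all libraries but the one with 8560 counts thinned to 1000000 counts, the 55 libraries of the authors' normalized table, limma on log2 of the authors' normalized values plus a pseudocount of 1, and the position on the main axis of spread within groups as a covariate, again without that library. This within-group axis held 12.4% of the variance within groups, its absolute cosine with the difference between the media was 0.631, and the media differed along it in the same direction at 9 of 9 times, so adjusting for it also removes part of any medium effect that lies along it. The comparisons of each medium's mean with the start were also added then. Other splits of the libraries were drawn up to 100 per result.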

Results

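The experiment followed gene expression in maize shoots after nitrogen-starved seedlings met nitrogen. Seedlings of the inbred line B73 were starved of nitrogen for 2 days and, 2 h after lights on, moved either to a nitrogen medium with 20 mM KNO3 and 20 mM NH4NO3 or to 20 mM KCl, which supplies potassium without nitrogen. The nitrogen medium carried a 10% 15N label. The media also differed in chloride and in total added salt, so effects of these cannot be told apart from those of nitrogen. Shoots were harvested at the start and at 9 times from 5 to 120 min after transfer, with 3 replicates per time and medium. Nitrogen libraries held a median of 2779326 counts and KCl libraries a median of 2006288. Library totals ran from 1057488 to 5684785, apart from nitrogen 120 min replicate 3, which held 8560 counts. Pairs of replicates without that library differed by more than sampling noise, with a chi-square of 1.457 to 9.169 per degree of freedom; its own pairs, at 0.989 and 0.991, hold too few counts to tell. Following the labels, each library was counted as a separate sample.

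The first question was which genes differed between nitrogen and KCl medium over the whole course. Plastid genes were lower in nitrogen than in KCl: all 7 tested plastid models were lower, with a median log2 change of -0.84, and 7 were called when adjusted over the group alone. The largest difference was in ndhD, which encodes a subunit of the plastid NADH dehydrogenase-like complex. It averaged 4.21 ± 7.68 scaled counts per 1000000 (CPM) in nitrogen (SD, n = 26) and 61.4 ± 27.4 CPM in KCl (n = 27), a log2 change of -4.81 (SE 0.325, adjusted p = 2.34e-17), and it was lower at 9 of 9 times. With the within-group axis as a covariate it was -3.12 (SE 0.427). The 3 start libraries averaged 32.6 ± 53.7 CPM for ndhD, with 1 library near the KCl level and the others near the nitrogen level. The ribosomal protein gene rps16 changed by -0.85 (SE 0.138) and the intron maturase gene matK by -0.72 (SE 0.121) on the log2 scale, each lower at 9 of 9 times. A model spanning psbK, psbI, psbD, psbC and psbZ, genes of photosystem II, changed by -1.75 (SE 0.161), and ndhA, another subunit of the NADH dehydrogenase-like complex, by -0.84 (SE 0.228), a call lost in 1 alternative. The smallest difference, -0.37 (SE 0.156, adjusted p = 0.0397) in a model spanning psaJ, rpl33, rps18, rpl20, clpP and rps12, was lower at 6 of 9 times and lost its call in 14 of 65 alternatives. Counts on plastid models made up 0.188% ± 0.0698 of a nitrogen library (SD, n = 26), 0.339% ± 0.0979 of a KCl library (n = 27) and 0.263% ± 0.135 of a start library (n = 3). The camera test placed the plastid group below other genes (adjusted p = 0.001), a call that was lost with an estimated correlation (adjusted p = 0.17 with an estimated correlation).

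Of 21 tested mitochondrial models 13 were higher in nitrogen than in KCl, 0 were lower and 8 did not pass the test, among them the most abundant, orf99-d, at a log2 change of -0.11 (SE 0.0929). The median log2 change was 0.435. The maturase gene mat-r averaged 25.1 ± 6.71 CPM in KCl (SD, n = 27), 39.8 ± 13.7 CPM in nitrogen (n = 26) and 45.9 ± 5.86 CPM at the start (n = 3), a log2 change between the media of 0.63 (SE 0.127, adjusted p = 3.57e-05). The ribosomal protein gene rps7 was higher in nitrogen by 0.60 (SE 0.132), with 16.97 ± 5.01 CPM in KCl, 26.8 ± 10.6 in nitrogen and 27.9 ± 1.65 at the start. Against the start, KCl was lower for mat-r (-0.89, SE 0.247, adjusted p = 0.013) and rps7 (-0.76, SE 0.259, adjusted p = 0.0468), and nitrogen did not pass for either (adjusted p = 0.709 and 0.85). Smaller differences were called for cox3, a cytochrome oxidase subunit, at 0.44 (SE 0.135), and for atp4, an ATP synthase subunit, at 0.29 (SE 0.1). With the within-group axis as a covariate these 4 calls were lost, as effects shrank and SEs grew: mat-r was at 0.47 (SE 0.196, adjusted p = 0.0738), rps7 at 0.32 (SE 0.199), cox3 at 0.16 (SE 0.215) and atp4 at 0.15 (SE 0.155). Of the 13 calls only that of orf119-c was kept with this covariate, but ccmB, at 0.71 (SE 0.229) before and 0.71 (SE 0.346) after, and orf734, at 0.57 (SE 0.23) and 0.82 (SE 0.345), lost theirs with a larger SE and no smaller effect. In all cox3 lost its call in 3 alternatives. The NADH dehydrogenase gene nad4 had a log2 change of 0.17 (SE 0.107) and did not pass. The whole mitochondrial share of counts was 0.404% ± 0.0979 in nitrogen (n = 26) and 0.394% ± 0.0664 in KCl (n = 27). For this group the camera test gave an adjusted p of 0.012, and 0.47 with an estimated correlation. Libraries of this kind are primed on poly(A), which organelle transcripts carry only in part, so these values describe the captured fraction.

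Among nuclear genes that met the rule for named genes apart from the name, since the files give them by ID alone, the largest positive difference was in Zm00001d018161 (chromosome 5, 215727084 to 215730071, minus strand). It averaged 57.4 ± 65.7 CPM in nitrogen (SD, n = 26) and 0.569 ± 1.19 CPM in KCl (n = 27), against 0.474 ± 0.264 CPM at the start (n = 3), and pooled CPM was 84.9-fold higher in nitrogen. Its level in nitrogen climbed from 0.52 CPM at 5 min through 8.50 at 20 min to 164.5 at 60 min. The late minus early test could not judge this gene (adjusted p = 1), 1 of 20 such genes, because groups with 0 counts in both parts of the course leave that contrast undetermined. Zm00001d026177 (chromosome 10, 140377176 to 140378531) averaged 28.1 ± 12.3 CPM in nitrogen, 1.48 ± 2.47 in KCl and 13.5 ± 5.11 at the start, a pooled ratio of 20.0. The largest negative differences were in Zm00001d024518 (chromosome 10, 75760691 to 75762808) and Zm00001d030786 (chromosome 1, 159716363 to 159727649). The first averaged 21.9 ± 9.03 CPM in KCl, 2.25 ± 3.12 in nitrogen and 9.78 ± 15.7 at the start, a log2 change between the media of -3.53 (SE 0.268). The second averaged 82.3 ± 51.97, 11.7 ± 19.5 and 26.7 ± 35.7 CPM, with -3.10 (SE 0.268). Against the start, the first was lower in nitrogen (-2.44, adjusted p = 0.00731) and did not pass in KCl (adjusted p = 0.0788). The second was higher in KCl (1.48, adjusted p = 0.0496) and did not pass in nitrogen (adjusted p = 0.18). For both genes the SD at the start exceeded the mean, so these comparisons rest on a start level that varied widely between its 3 libraries. With the within-group axis as a covariate both differences between the media shrank, to -2.02 and -1.86, and stayed called (adjusted p = 8.8e-06 and 0.000239).

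**Figure D1:**
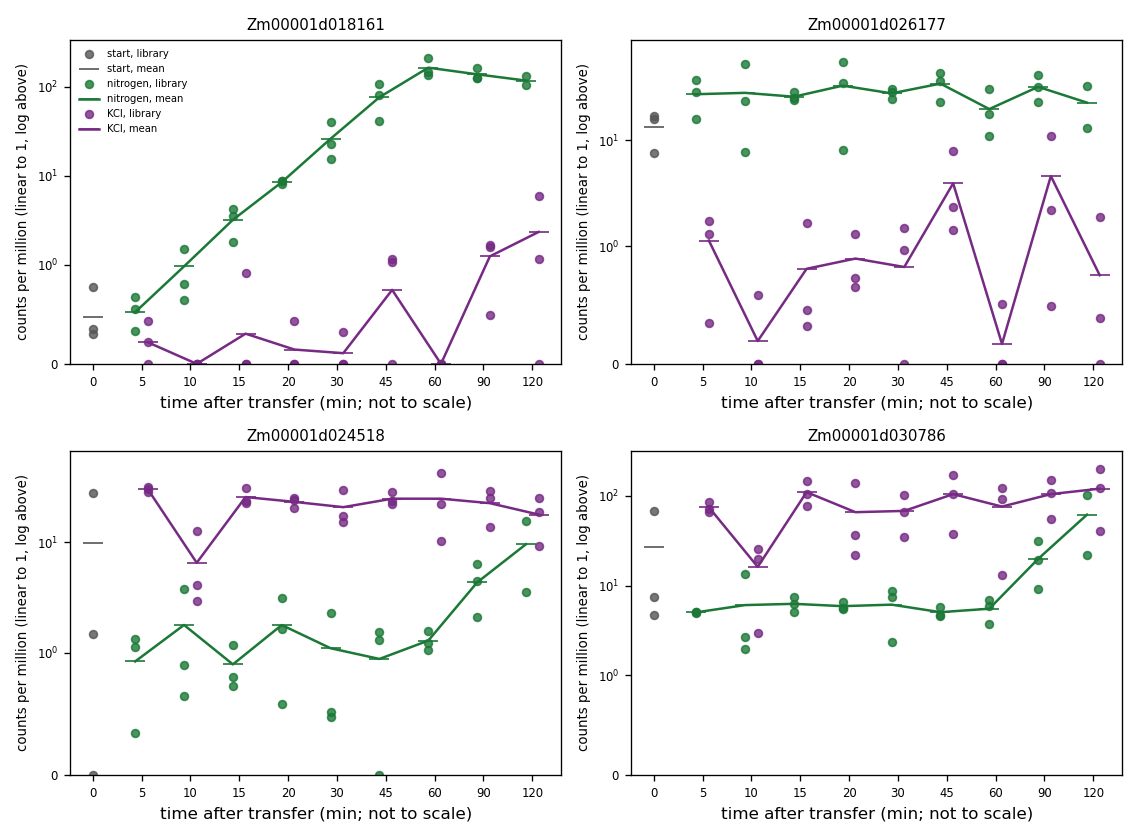
Level of the 4 nuclear genes named for the average effect in each library, in CPM (linear to 1, log above), against time after transfer in min (not to scale). Points are libraries and lines join group means for nitrogen, KCl and start; Zm00001d018161 climbs in nitrogen to a mean of 164.5 at 60 min while its KCl mean over all times is 0.569.

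**Figure D2:**
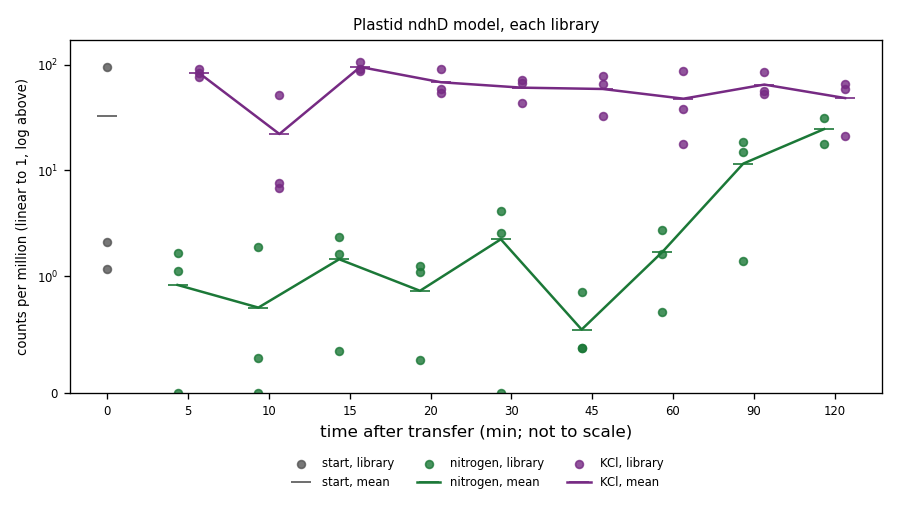
Level of the plastid ndhD model in each library, in CPM (linear to 1, log above), against time after transfer in min (not to scale). Points are libraries and lines join group means; 22 of 26 nitrogen libraries lie below the lowest KCl library, and the 3 start libraries stand at 1.17, 2.08 and 94.7.

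Across all 18412 tested genes, 10830 differed between the media on average, 5509 higher and 5321 lower in nitrogen. Which direction was the more frequent depended on the processing, with 4818 higher and 5888 lower under RLE size factors, 5129 and 5639 under library totals, 4106 and 5152 under DESeq2 and 4653 and 4706 with a mean of at least 5 CPM. The 55 libraries of the authors' normalized table gave 5259 and 5549, and leaving out 1 library turned the balance in most cases. Most differences were small: the median absolute log2 change of called genes was 0.361, and 783 changed over 2-fold, 220 of them higher and 563 lower. With the 9 times tested jointly 8637 genes were called. Regulators of the authors' network table were higher in 86 and lower in 68 of 203 cases (camera adjusted p = 0.3), with 156 called when adjusted over the group alone, and its other targets were higher in 867 and lower in 1050 of 2529 cases (adjusted p = 0.096). The authors' choice of these groups may rest on the same samples, so their counts may not be independent evidence. Of 138 other nuclear non-coding RNA genes 43 were higher and 22 lower (adjusted p = 0.29). With the within-group axis as a covariate and without the library of 8560 counts the count of 10830 became 4335, against 10990 without that library alone.

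The start libraries give the background for these differences. Along the axis that separated the media at 10 to 120 min, scaled so that the KCl 5 min mean is 0% and the nitrogen 5 min mean 100%, the 3 start libraries lay at 84%, 71.3% and 24%. The position of the KCl groups stayed between -29.4% and 19% after 5 min. Nitrogen groups moved from 93.6% at 10 min to 124% at 60 min, then to 60.8% at 90 min and 34.6% at 120 min. Libraries at 10 min and later, apart from the one with 8560 counts, were used to draw the axis, so their separation is partly built in, whereas the start and 5 min libraries were not used for it.

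**Figure D3:**
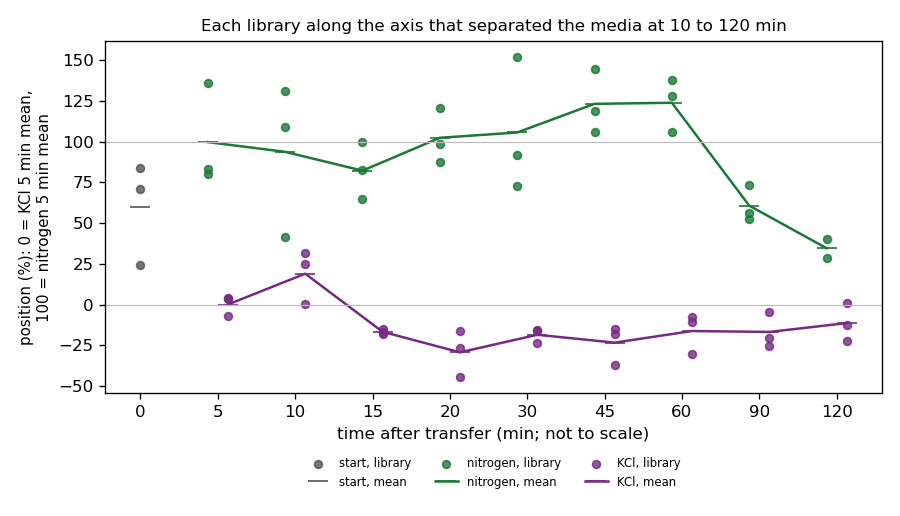
Position of each library in percent along the axis that separated nitrogen from KCl at 10 to 120 min, against time after transfer in min (not to scale). Points are libraries and lines join group means; the nitrogen mean falls to 34.6% at 120 min, and start libraries lie at 84%, 71.3% and 24%.

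The design also asks when the media differed. The level of ndhD was 0.92 ± 0.844 CPM in nitrogen against 84.5 ± 7.24 in KCl at 5 min (SD, n = 3 each) and 0.54 ± 0.276 against 59.2 ± 23.3 at 45 min. It was 0.732 ± 1.02 CPM in nitrogen against 22.2 ± 25.9 in KCl at 10 min, 2.23 ± 2.09 against 60.9 ± 15.4 at 30 min, 1.70 ± 1.03 against 47.9 ± 36.1 at 60 min, 11.6 ± 9.02 against 65.1 ± 18.2 at 90 min and 24.7 ± 9.88 (n = 2) against 48.5 ± 23.8 at 120 min. At 5 min 3319 genes differed, 1532 higher and 1787 lower in nitrogen. The numbers called were 51 at 10 min, 1412 at 15 min, 4913 at 20 min, 2630 at 30 min, 4355 at 45 min, 3795 at 60 min, 1217 at 90 min and 197 at 120 min. The direction of calls at 5 min moved with the scaling: 46.2% were higher with TMM, 30.2% with RLE size factors (938 higher, 2173 lower) and 28.6% with library totals (904 higher, 2258 lower). With library totals, 36.6% were higher at 60 min (1393 of 3805 calls) against 47% with TMM, and 59.9% at 90 min (759 of 1267) against 49.1%. Across 15451 genes, which are not independent replicates, the differences at 5 and 45 min correlated at r = 0.731 (Spearman 0.665) and those at 45 and 120 min at r = 0.342 (Spearman 0.291), 2 of 36 pairs of times compared without shared libraries. Each count rests on 3 libraries per medium at most, and at every time leaving out 1 library moved it by over 1.5 times in at least 1 case, to between 722 and 3394 at 5 min, 0 and 1178 at 10 min, 629 and 2930 at 30 min and 59 and 422 at 120 min. With the within-group axis as a covariate the count at 5 min was 132.

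**Figure D4:**
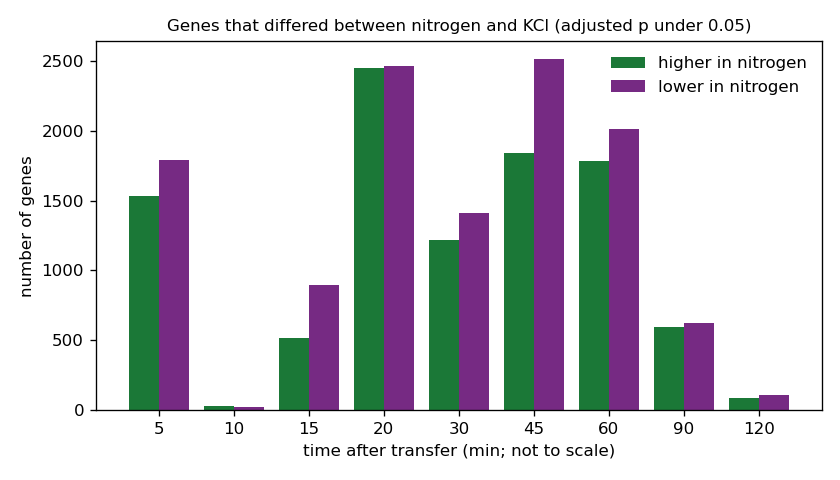
Number of genes that differed between nitrogen and KCl at each time after transfer in min (not to scale), with an adjusted p under 0.05. Bars give genes higher and lower in nitrogen; 4913 genes were called at 20 min and 197 at 120 min.

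Nuclear genes whose response changed over the course were found by testing the late minus the early difference directly. Zm00001d044138 (chromosome 3, 220166617 to 220170536, minus strand) rose in nitrogen from 5.82 ± 0.681 CPM at 5 min through 71.3 ± 12.4 at 20 min to 624.5 ± 148 at 60 min (SD, n = 3), while its mean over KCl libraries was 5.61 ± 3.34 (n = 27); late minus early was 3.29 (SE 0.364, adjusted p = 9.39e-09). Zm00001d033543 (chromosome 1, 266535576 to 266537890) stood at 1.62 ± 0.768 CPM at 5 min and 63.2 ± 8.72 at 90 min in nitrogen, with 2.81 ± 1.15 over KCl libraries, and late minus early was 3.27 (SE 0.264, adjusted p = 2.7e-13). Zm00001d028750 (chromosome 1, 45286331 to 45290076) was above KCl at 5 min, 153.6 ± 24.7 against 55.8 ± 36.8 CPM, and below it at 60 min, 63.3 ± 33.3 against 123 ± 29.6, a late minus early change of -1.57 (SE 0.33, adjusted p = 0.00436). For Zm00001d053554 (chromosome 4, 233852901 to 233854306) the change was -1.65 (SE 0.424, adjusted p = 0.0313), a call lost in 11 of 65 alternatives. The late minus early difference of ndhD, 1.95 (SE 1.15), did not pass, while the SEs of its early and late means were 0.454 and 0.46. In all, 260 genes passed, 103 with a higher and 157 with a lower late difference, a balance that turned to 64 and 59 with DESeq2, 72 and 57 with thinned counts and 100 and 92 with those 55 libraries. The early mean alone called 9141 genes and the late mean 7236. The count of 260 became 165 without nitrogen 120 min replicate 2 and 123 with DESeq2.

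KCl medium itself was compared with the start to show what moved without nitrogen. This comparison also spans the transfer itself and the passing hours of the morning. Their effects cannot be told apart from those of KCl medium. Zm00001d024522 (chromosome 10, 75943680 to 75945921) rose from 11.9 ± 7.18 CPM at the start to 193.9 ± 43.6 at 120 min in KCl (SD, n = 3 each), a log2 change of 4.0 (SE 0.495, adjusted p = 1.34e-07). In nitrogen it stood at 114 ± 97.8 CPM at 120 min (n = 2), against a mean of 18 ± 35.1 CPM over all nitrogen libraries (n = 26). Zm00001d026177, higher in nitrogen on average, stood at 13.5 ± 5.11 CPM at the start and 0.754 ± 0.989 CPM at 120 min in KCl (log2 change -3.75, SE 0.833, adjusted p = 0.00163), a call lost in 1 of 18 alternatives. Its level in KCl was already 1.13 ± 0.714 CPM at 5 min, so the difference from the start did not build up over the course. Zm00001d021208 (chromosome 7, 146038525 to 146039307) went from 0.215 ± 0.188 to 3.05 ± 3.23 CPM and Zm00001d017485 (chromosome 5, 197280407 to 197281892) from 8.94 ± 3.22 to 0.357 ± 0.618 CPM, and the calls of both were lost in 9 alternatives each. In KCl at 5 min Zm00001d017485 was already at 0.81 ± 0.448 CPM. Zm00001d021208 was above the start in nitrogen too (mean log2 change 4.63, SE 0.935, adjusted p = 0.00478). Between the media it did not pass on average (0.12, SE 0.237, adjusted p = 0.682). Network regulators rose in 36 and fell in 11 of 203 cases at 120 min (camera adjusted p = 0.039, and 0.074 with an estimated correlation), 55 being called when adjusted over the group alone. Of the plastid models 1 of 7 rose, the one spanning psbK to psbZ, with a log2 change of 1.20 (SE 0.393, adjusted p = 0.0366), and of the mitochondrial models 1 of 21 fell, orf140-b, with a log2 change of -0.86 (SE 0.28, adjusted p = 0.0349), though 0 mitochondrial models were called when adjusted over the group alone. In KCl medium 1996 genes differed from the start at any time, 575 at 30 min and 2061 at 120 min, the last with 1201 higher and 860 lower. The counts did not grow steadily with time: 24 genes were called at 10 min, 2617 at 20 min, the most of any time, and 510 at 60 min. At 20 min KCl replicate 3 differed from its mates at a chi-square of 6.066 and 8.747 per degree of freedom. The KCl groups of 10 and 60 min held libraries of only 1057488 and 1116220 counts. The parts of single libraries and of depth in these counts were not tested. Leaving out 1 library moved the count at 30 min to between 134 and 1030 and the count at 120 min to between 835 and 2483.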

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

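Tests chosen only after the result was seen were those of the start libraries' position and of their spread, of the other plastid models, of the spread within groups, of the size of the effects at 5 min, of other splits at equal depth, of depth as a covariate, and the thinned counts and within-group axis themselves. For depth as a covariate and for the number called with thinned counts or the within-group axis, the bounds were nevertheless written before those tests were run.

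The nitrogen effect differed between the late and the early part of the course for 260 genes, by a test of the difference itself. Among those named, late minus early was 3.29 for Zm00001d044138, 3.27 for Zm00001d033543, -1.65 for Zm00001d053554 and -1.57 for Zm00001d028750 on the log2 scale. In 1 of 100 splits that mixed the media within each time, the real one, as many genes passed, and the highest other split gave 42. Such splits mix away the whole medium effect, not only its change over time, and add it to the spread within groups. They therefore cannot decide whether chance gave the count at an adjusted p under 0.05. At an unadjusted p under 0.05 the real split gave 2303 genes and other splits up to 4359, so chance cannot be excluded for that count.

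The first pattern is that 3319 genes already differed 5 min after transfer. A difference in the number of counts as such is argued against as the whole cause, because with the libraries thinned to equal depth 1264 genes were still called. The other splits of the 6 libraries called 0, with up to 1438 at an unadjusted p under 0.05 against 3601. Mixing the media adds their difference to the spread, though, and 10 splits are too few for a share under 0.05. A bias in the ratios of counts that came with depth would survive thinning. The part of depth in the remaining calls stays open: 1264 lies below the bound of 50% set beforehand for depth as the cause, but fewer counts lower the number in any case, a slope of 1.01 of thinned on full effects over 3073 genes follows from thinning itself, and a slope of 0.993 with the library total as a covariate decides nothing, since 0 genes were called for that covariate. The main axis of spread within groups stays open: with it as a covariate 132 genes were called and effects shrank to a slope of 0.552, the median absolute log2 change going from 0.704 to 0.377 at a median SE of 0.199 before and 0.2 after, although such a covariate may also remove a real response that lies along it. The start libraries, which met neither medium, lay on average at 59.8% of the way from KCl to nitrogen and did not all fall on one side, so which medium moved the shoots cannot be told apart; across genes the main axis of the start libraries' own spread went with the medium effect at an absolute r of 0.533. Over 18 groups absolute r ranged from 0.00604 to 0.575 with a median of 0.158, and the 6 groups over 0.3 were the start and 5 nitrogen groups while no KCl group was over 0.198, so a state that varies between shoots of the start and of some nitrogen groups, or a difference in handling or library preparation that the labels do not give, may account for part of the pattern, and a response to nitrogen within 5 min remains open as well.

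The second pattern is the low level of the plastid ndhD model in nitrogen. A lower yield of plastid RNA as a whole is argued against as the sole cause, since the median log2 effect of the other plastid models was -0.778 (range -1.75 to -0.37) against -4.81 for ndhD. The within-group axis left -3.12 (SE 0.427), and the smallest effect on leaving out 1 library was -4.64. Reads from an overlapping or antisense transcript were not tested, and neither was a difference in polyadenylation, on which capture of plastid RNA depends. Since 1 of the 3 start libraries stood near the KCl level and the others near the nitrogen level, a response of ndhD to nitrogen is a hypothesis that stays open.

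The third pattern is that fewer genes were called at 90 and 120 min than at 20 to 60 min. With the within-group axis as a covariate 1616 genes were called at 90 min, more than at 30, 45 or 60 min, so there the pattern held only against 20 min. The 319 genes at 120 min were still the fewest from 20 min on, but lay near the 372 at 45 min. The loss of 1 library at 120 min is argued against as the sole cause, because at 45 min the lowest count without 1 library was still 2552, against 197 at 120 min. A larger spread within groups could not be judged by the SD of log2 CPM. Each gene's test used 1 estimate of spread pooled over all 19 groups, not that of a single time. Averaged over the media the SD was 0.223 at 90 and 0.234 at 120 min, below the 0.265 at 20, 0.247 at 30 and 0.266 at 60 min. Both lay above the 0.216 at 5 and 0.204 at 15 min, and 120 min lay above the 0.225 at 45 min. The nitrogen SD at 120 min, 0.183, came from 2 libraries, and SDs of 2 values tend to be lower than SDs of 3. KCl alone had 0.249 at 90 min, above its 0.177, 0.21, 0.215 and 0.231 at 5, 15, 30 and 45 min. At 120 min KCl had 0.285, the highest of any group. Effects had a slope on those at 45 min of 0.378 at 90 min and 0.199 at 120 min, and of 0.372 at 10 min, where nitrogen replicate 3 lay at 41.5% of the way from KCl to nitrogen, its mates at 131% and 109%, and leaving it out took the count from 51 to 1178. The within-group axis and a larger spread within groups stay open, and so does a smaller late difference between the media, since the library groups of each time may differ in ways the labels do not give.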

How the results depend on the processing

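Alternatives chosen after the data were seen are the thinned counts, the 55 libraries of the authors' normalized table, limma on the authors' normalized values, the within-group axis, and all alternatives of the comparisons of a medium's mean with the start and of the added gene groups.

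Under RLE size factors, library totals, limma-voom and a mean of at least 5 CPM, each count of genes stayed within 1.5 times its value, and so did the joint count under the spline of time, which was run for that count alone. The replicate numbers do not pair the libraries: of 26 same-numbered pairs 3 correlated over 0.1 (r from -0.19 to 0.229), and 16 of 53 libraries correlated best with their own number. With the replicate number as a block the average count was 10819, the joint count 8582 and the count at 5 min 3256, and no count moved by over 1.5 times. For named genes and the other tested organelle models, 40 values under 2395 alternatives in all gave 2297 with the same call, 83 weaker, 15 stronger and 0 reversed. Most of these alternatives left out 1 library each, 54 of them per value for the average, so the total says little about the processing. Values that did not pass could change sign without being counted as reversed, as nad4 did, from 0.17 to -0.14 with the within-group axis as a covariate. The cause of the changes listed next was not tested, except that thinning and leaving out libraries lower the counts available. Gene-list alternatives, alternatives for KCl minus start at 10, 20 and 60 min and for nitrogen minus start at single times, for single organelle models in either medium against the start, and the use of 6 libraries for the average effect, which spans 18 groups, were not run. At single times 14% (60 min) to 25% (45 min) of simulated 1.5-fold changes between the media were recovered, against 99% for the average; the parts of depth and of the number of libraries were not separated.

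Without a filter 634 genes were called for late minus early, 662 at 10 min, 558 at 120 min, 3468 for KCl at any time, 983 for KCl at 30 min and 587 for nitrogen minus start. DESeq2 called 123 for late minus early, 1576 at 5 min, 668 at 15, 2998 at 20, 1289 at 30, 2718 at 45, 2390 at 60, 515 at 90 and 90 at 120 min. For KCl it called 1057 at any time, 235 at 30 and 1028 at 120 min and 947 for the mean, and 46 for nitrogen minus start. With only the 6 libraries compared the counts were 4 at 10 min, 2395 at 15, 2730 at 20 and 1938 at 90 min, and 1053 and 478 for KCl at 30 and 120 min. The 55 libraries gave 105 at 10 min, 90 at 120 min and 904 for KCl at 120 min, and limma on the authors' normalized values gave 303, 96 and 1022. Thinned counts gave 5714 jointly, 4796 late, 129 for late minus early, 1264 at 5 min, 623 at 15, 2703 at 20, 1433 at 30, 2627 at 45, 2502 at 60, 605 at 90 and 96 at 120 min. For KCl they gave 1010 at any time, 253 at 30 and 978 at 120 min and 1001 for the mean, and 47 for nitrogen minus start. With the within-group axis as a covariate the counts were 4335 on average, 2857 jointly, 3442 early, 3192 late, 400 for late minus early, 132 at 5 min, 21 at 10, 402 at 15, 2955 at 20, 603 at 30, 372 at 45, 526 at 60 and 319 at 120 min. Of the 4335 genes, 3717 were among the 10830, and 3683 of these had the same direction. For the added gene groups, camera with an estimated correlation called 0 on the average effect (0 at an unadjusted p under 0.05) and 0 for KCl at 120 min (1 unadjusted), and fry called 4 and 1.

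Leaving out 1 library at a time gave 10595 to 11142 genes on average, 8230 to 9082 jointly, 8605 to 9567 early, 6628 to 7390 late and 165 to 333 for late minus early (165 without nitrogen 120 min replicate 2). At 5 min the range was 722 to 3394, with 722 without nitrogen replicate 3, 1868 without KCl 2 and 2207 without KCl 3. At 10 min it was 0 to 1178, with 1 without nitrogen 1, 18 without nitrogen 2, 1178 without nitrogen 3, 1 without KCl 2 and 0 without KCl 3, where edgeR gave 2438 genes at an unadjusted p under 0.05. At 15 min it was 518 to 1412, with 836 and 518 without nitrogen 1 and 3 and 869, 739 and 920 without KCl 1, 2 and 3. At 20 min it was 2639 (without KCl 3) to 4686, and at 30 min 629 (without nitrogen 3) to 2930, with 1207 without KCl 1. At 45 min it was 2552 (without nitrogen 2) to 3998, with 2837 without KCl 2. At 60 min it was 2173 (without nitrogen 1) to 3985, with 2389 and 2324 without KCl 1 and 2. At 90 min it was 370 (without nitrogen 3) to 949, with 635 without nitrogen 1 and 403 and 682 without KCl 1 and 2. At 120 min it was 59 (without nitrogen 2) to 422 (without KCl 2), with 84 without nitrogen 1 and 94 without KCl 3. For KCl at any time the range was 1325 (without start 1) to 2237. For KCl at 30 min it was 134 to 1030, with 145, 205 and 1030 without start 1, 2 and 3 and 134, 274 and 288 without KCl 1, 2 and 3. For KCl at 120 min it was 835 (without KCl 3) to 2483, with 1059 and 1338 without start 1 and 2. Nitrogen minus start ranged from 33 (without start 3) to 268 (without nitrogen 10 min replicate 3), and KCl minus start from 436 (without start 1) to 2244, with 663 without start 2.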

Other observations

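The comparisons of each medium's mean with the start and the tests of the added gene groups were chosen after the data were seen, whereas the tests of regulators, of neighbouring genes and of other splits were set before their own results were seen. For neighbouring genes only Pearson's r over all pairs was set before, and the shuffles of the other measures were added later.

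Each medium was also set against the start. Averaged over 9 times, 96 genes differed between nitrogen and the start, 65 higher and 31 lower, and 2054 differed between KCl and the start, 884 higher and 1170 lower. Of the single times only 60 min broke this order, with 868 genes for nitrogen and 510 for KCl, whereas the counts were 341 and 907 at 45 min and 275 and 2061 at 120 min. Zm00001d018161 averaged 57.4 CPM in nitrogen against 0.474 at the start, whereas Zm00001d026177 stood at 28.1 CPM in nitrogen, 13.5 at the start and 1.48 in KCl. Both comparisons share the same 3 start libraries, so their counts carry common chance values. Leaving out start replicate 3 gave 33 genes for nitrogen, leaving out nitrogen 10 min replicate 3 gave 268, and leaving out start replicate 1 or 2 gave 436 or 663 genes for KCl.

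The authors' network table held 554596 pairs of 203 regulators and 2732 targets. Of all weights 34.7% were 0, and the top 1% of pairs held 35% of the summed weight. A regulator had weight on 44 to 2685 targets, and its summed weight ran from 4.27 to 2670. Of the regulators 75.9% and of the other targets 75.8% differed between the media on average, against 55.9% of the remaining tested genes. The table's making is not given in the sources used here, so whether these shares are independent of the samples is not known.

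The hypothesis that regulators with a higher summed weight respond more to nitrogen was negative by the test set for it: across 203 regulators the Spearman rho between weight and the absolute effect was 0.124 (permutation p = 0.079). Pearson's r was 0.153 (permutation p = 0.031), and 0.141 without the 2 farthest regulators, 1 relation being tested. The hypothesis that neighbouring genes respond alike missed the bound set for it, since r between 18241 neighbouring pairs was 0.0229 and the highest of 1000 shuffles reached 0.0256, though only 1 shuffle was as high. Spearman's rho was 0.0387, above every shuffle (highest 0.0222). For pairs under 10000 bp apart r was 0.0332 (9 shuffles as high), and for pairs on the same strand it was 0.0323 (1 as high). A weak likeness between neighbours therefore stays open.

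Other splits of the libraries were tested for the counts below, but not for nitrogen minus start at single times or for KCl minus start at times other than 30 and 120 min. For 100 splits that mixed the media within each time, the average count of 10830 was reached by 1 split, the real one, with 1716 as the highest other, the joint count of 8637 by 1 with 810, the early count of 9141 by 1 with 1, and the late count of 7236 by 1 with 2883. For KCl medium and the start, the joint count of 1996 was reached by 1 of 100 splits with 448 as the highest other, and the mean count of 2054 by 1 of 100 with 568. Chance is therefore argued against as the source of each of these 6 counts as a whole, not gene by gene. At an unadjusted p under 0.05 the real split also called more genes. Late it called 8705 against up to 6259, and for the KCl mean 4770 against up to 3563. Mixing the groups adds their difference to the spread, though, which widens the gap. Without start replicate 1 the KCl mean count was 436, below that 568, and no splits were drawn without it. For nitrogen minus start, 7 of 100 splits reached 96, the highest other calling 2590, so chance cannot be excluded, and a split that calls so many points to a structure among the libraries, whose source was not tested. For the added gene groups on the average effect, 42 of 100 splits called as many as the 2 called, with 3 as the highest other, so chance cannot be excluded.

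At single times 3 libraries against 3 make 10 splits, too few for a share under 0.05. The number reaching the real count, the real split included, was 1 at 5 min (real 3319, highest other 0 with up to 1838 genes at an unadjusted p under 0.05 in edgeR), 3 at 10 min (51, highest other 465), 1 at 15 min (1412, highest other 1) and 1 at 20 min (4913, highest other 342). It was 1 at 30 min (2630, highest other 1), 1 at 45 min (4355, highest other 1), 1 at 60 min (3795, highest other 8), 1 at 90 min (1217, highest other 0 with up to 1430 at an unadjusted p under 0.05 in edgeR) and 2 at 120 min (197, highest other 392). For KCl minus start it was 1 at 30 min (575, highest other 25) and 1 at 120 min (2061, highest other 549), and for the added gene groups at 120 min 5 (real 1, highest other 2).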
